A study of Solanum lycopersicum with 8 samples.

How the data were processed

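Leaf RNA of 28 day old tomato plants was measured on 8 Affymetrix tomato arrays, 4 labelled as an antisense line against 2-oxoglutarate dehydrogenase and 4 labelled wild type. The labels name the variety MoneyMaker and number 4 replicates per genotype, whereas the series text names the variety M82 and 3 replicates per genotype, which it calls biological, and this difference was not resolved here. Each array's group and replicate number were taken from its title. The labels do not say which arrays came from separate plants, so the p-values measure the spread between these samples, which may be partly technical.

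The deposited values were used as log2 probe set signals, as the authors' table gives them. The log base is not given in the sources used here, and log2 was inferred from the range of the values and from column medians near 8.7. MAS5, GCOS and RMA are named per the submitters' processing notes, with no role or order, so the background and scaling steps stay unknown. No scanner files were used here. The number of arrays limits the precision. The table held 10209 probe sets, of which 10038 tomato probe sets were tested, and 108 control and 63 reporter probe sets were left out of the tests. The reporter probe sets had mean signals up to 6.71. Whether tomato signals below that level lie above background was not tested, so differences that involve them are of uncertain size. In the annotation used here 909 tomato probe sets had 1 gene symbol, none had several, and 9129 were unnamed. The 909 carried 802 different symbols, and 885 of them matched the gene table of assembly SLM_r2.1 by gene ID. That table was used for names and synonyms only. No probe set was named as an oxoglutarate dehydrogenase gene in this annotation, so the transcript targeted by the antisense construct was not analysed here.

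Arrays were compared before any test of genotype. For each pair, the robust SD (a scaled median absolute deviation) of the log2 differences was taken over the 4559 tomato probe sets with a mean above 9, and over 59 control probe sets for bacterial and tag sequences. Arrays of 1 genotype whose bright probe sets differed by less than the control probe sets (a ratio under 1) were averaged and counted as 1 sample. The bright probe sets have less noise than the dim controls, so this rule leans towards calling arrays alike. The rule and its limit were set after the differences between arrays had been seen. It left 2 antisense samples (arrays 1 to 3 averaged, and array 4) and 3 wild type samples (array 1, arrays 2 to 3 averaged, and array 4). The fit chosen before the data were examined used all 8 arrays as separate samples. That the 5 sample fit leads here was settled after both counts had been seen, and the 8 array result is printed beside it.

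Genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 10038 probe sets and a threshold of 0.05. All adjusted p-values of single probe sets are limma's. Differences are antisense minus wild type on the log2 scale, with limma's moderated standard error. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 5 probe sets, and again with an estimated correlation and with fry. The 31 themes and the symbol patterns that fill them were fixed before the data were examined, and 17 of them held enough probe sets. Some patterns caught genes outside their theme, among them the proline transporters ProT1, ProT2 and ProT3, profilin and the receptor-like kinases PRK1, PRK2 and PRK3 in the defence list, the kinases PPCK1 and PPCK2 in the glycolysis list, and the chitinases CHI14 and CHI17 in the phenylpropanoid list. Other patterns missed genes, and the tricarboxylic acid cycle pattern matched none. A version of the lists with members reassigned from gene symbols was drawn up after the first ranking of genes had been seen. It tested 24 lists and is given as an alternative only.

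Genes were named by a rule fixed before the data were examined. It took the 12 largest differences per direction among named genes with an adjusted p under 0.05 and no overlap between genotypes, or the 5 of smallest p per direction where fewer than 5 passed, and up to 4 members of smallest p per list. In the 5 sample fit none passed, so the 5 of smallest p apply, and the rule was also run on the 8 array fit. Array quality was compared between genotypes by exact two-sided permutation tests of the sample means, with 3' and 5' control probe sets of actin, ef1a and gapdh. With 2 against 3 samples the smallest p such a test can give is 0.1. A group of 4 array-level values was examined for a value standing apart with Dixon's ratio at its critical value.

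The fits were tested on simulated data with the spread between samples and between near-identical arrays of these data, with probe sets drawn independently. Each probe set's spread was limma's moderated estimate, which varies less between probe sets than the unmoderated one. Of 100 probe sets moved by a log2 size of 1, the 5 sample fit recovered 89%, and of 100 moved by 2 it recovered 99%, with 12 false calls among the unchanged probe sets. The 8 array fit recovered 97% and 100%, with 321 false calls. These shares do not show that a change of such a size would pass in the real data. There Dea1, at -1.27, did not pass over 5 samples. In a simulated shift of 0.5 in 1 list of 42 probe sets, that list passed and none of the other lists did. The 2 lists that passed in the real data had smaller medians, -0.19 in 6 probe sets and 0.21 in 14. With probe sets drawn independently, the simulation could not show the effect of correlation within a list. Alternatives tried, on the 5 samples and the 8 arrays, were quantile normalization, subtraction of each array's median, leaving out the lowest 25% or 50% of probe sets by mean, a trended and robust prior, array weights, an unequal-variance test per probe set, a log2 size of at least 1, leaving out probe sets with suffix _x_at or _s_at, leaving out each replicate, and the replicate number as a block. Alternatives added later were the RNA sample (each of the 5 counted samples) as a random block, leaving out whole sets of near-identical arrays, and the 3' minus 5' difference as a covariate. That near-identical arrays share 1 RNA was inferred from their values, and the labels do not say it. Pseudocounts did not apply to values already on a log scale.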

Results

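The data were the deposited log2 signals of 10038 tomato probe sets in leaves of an antisense line against 2-oxoglutarate dehydrogenase, an enzyme of the tricarboxylic acid cycle, and of wild type plants. The comparison asks which leaf transcripts differ between the antisense line and the wild type. There were 4 arrays per genotype. Median signals lay between 8.72 and 8.78 on every array.

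Some arrays of 1 genotype were nearly identical. Antisense arrays 1, 2 and 3, and wild type arrays 2 and 3, formed 4 pairs whose bright probe sets differed with a robust SD of 0.0569 to 0.0688, below the 0.0948 to 0.127 of control probe sets in the same pairs. The other 8 pairs within a genotype differed by 0.139 to 0.215, and the 16 pairs between genotypes by 0.182 to 0.228. The near-identical arrays thus differed by less than the measurement noise of the controls and were counted as 1 sample each, which left 2 antisense and 3 wild type samples.

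**Figure D1:**
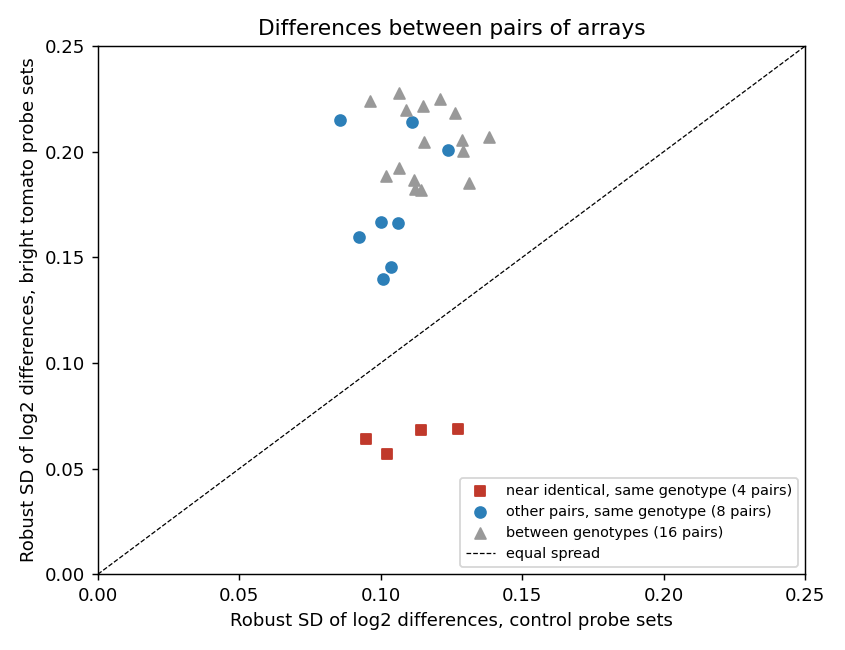
Robust SD of log2 differences between 2 arrays, over bright tomato probe sets (vertical axis) and control probe sets (horizontal axis). Each point is a pair of arrays, and 4 pairs of the same genotype lie below the line of equal spread.

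The named genes of smallest p were Dea1, PPCK1, PTI6, NML2 and LOC543862 among those lower in antisense and TGAS118, VDE, XTH6, PTPKIS1 and ail among those higher, and none passed adjustment over all probe sets. Dea1 had a log2 signal of 11.27 ± 0.02 (SD, n = 2) in antisense and 12.54 ± 0.12 (SD, n = 3) in wild type, a difference of -1.27 (standard error 0.0984, limma adjusted p = 0.268). PPCK1, a kinase that phosphorylates phosphoenolpyruvate carboxylase, read 8.63 ± 0.14 against 10.04 ± 0.26, a difference of -1.41 (adjusted p = 0.391). PTI6 was lower by value, with a difference of -0.54, as were NML2 at -0.73 and LOC543862 at -1.27. Among genes higher by value, XTH6, a xyloglucan endotransglucosylase of the cell wall, differed by 0.88, TGAS118 by 0.87, and ail by 0.60. VDE, the violaxanthin de-epoxidase of the xanthophyll cycle, differed by 0.49, and PTPKIS1 by 0.36. In each of these genes both antisense samples lay outside the range of the 3 wild type samples. The same held for 28.7% of all probe sets, where chance gives 20%. VDE (6.14 in antisense, 5.65 in wild type) and LOC543862 (5.33 and 6.60) had mean signals below the 6.71 reached by reporter probe sets.

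In limma's 5 sample fit 0 of the 10038 probe sets passed, 932 had an unadjusted p under 0.05, and chance would give about 502. Without antisense array 4 the 932 became 476, below that chance count, and without wild type array 1 it became 1409. Of the 932, 411 were higher and 521 lower, a split that turned to 505 and 466 under quantile normalization and to 507 and 445 with each array's median subtracted. An unequal-variance test per probe set also called 0, but with 2 antisense samples it has few degrees of freedom and could hardly call any. With all 8 arrays as separate samples, the fit chosen before the data were examined, 844 probe sets passed, 340 higher and 504 lower in antisense. Under quantile normalization that split became 442 higher and 427 lower. With the RNA sample as a random block, 32 passed, 16 in each direction, in a fit that still takes its degrees of freedom from all 8 arrays. The 8 array count treats near-identical arrays as independent. Without antisense array 1 or 2 it was 128 or 124, without antisense array 3 it was 197, without wild type array 2 or 3 it was 251 or 293, and without wild type array 1 it was 1817.

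**Figure D2:**
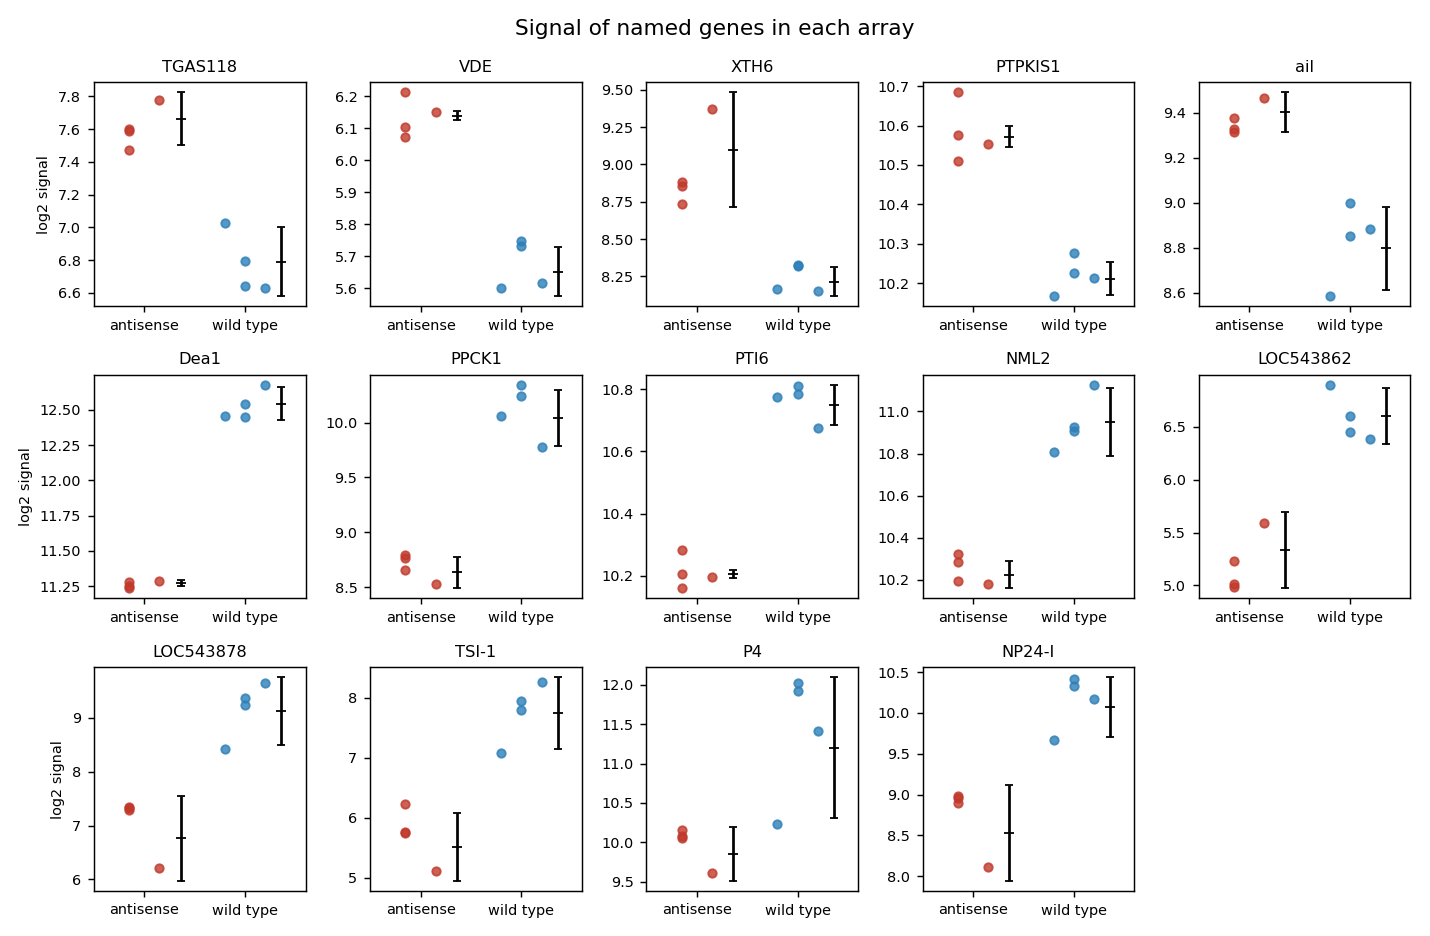
Log2 signal (vertical axis) of named genes in each of the 8 arrays, with near-identical arrays stacked in 1 column and the mean ± SD over 2 antisense or 3 wild type samples beside them. In Dea1 the antisense arrays sit near 11.27 and the wild type samples average 12.54.

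Among the named genes that passed with 8 arrays, the most negative differences over 5 samples were in LOC543878, TSI-1, DES and NP24-I. LOC543878, listed with the synonym PR5, read 6.76 ± 0.79 (SD, n = 2) in antisense and 9.12 ± 0.63 (SD, n = 3) in wild type, a difference of -2.35. TSI-1 differed by -2.22, DES, a divinyl ether synthase, by -1.76, NP24-I, an osmotin-like protein, by -1.54, and P4, a pathogenesis-related protein, by -1.35. The antisense means of TSI-1 and DES, 5.51 and 4.18, and the wild type mean of DES, 5.94, lay below the 6.71 reached by reporter probe sets. The sizes of these differences, and their rank, are thus uncertain. The limma adjusted p-values of LOC543878, TSI-1, DES, NP24-I and P4 were 0.439, 0.404, 0.504, 0.459 and 0.516 over 5 samples, and 0.0110, 0.00828, 0.0332, 0.0127 and 0.0469 over 8 arrays. With the RNA sample as a random block, LOC543878 and NP24-I passed (adjusted p = 0.0421 and 0.0488), as did Dea1, PPCK1, NML2 and LOC544312, all lower. That fit takes its degrees of freedom from the 8 arrays, so these passes still rest partly on near-identical arrays. Wild type array 1 read 10.23 for P4, next to the 9.61 to 10.15 of the antisense arrays, while wild type arrays 2 to 4 read 11.41 to 12.02. For DES wild type array 1 read 4.69, the antisense arrays 4.02 to 4.60 and wild type arrays 2 to 4 6.21 to 6.89. That array also had the lowest wild type signals of LOC543878, TSI-1 and NP24-I, and the highest 3' minus 5' difference of control transcripts among the wild type arrays, at 0.69. The fixed defence list of 27 probe sets had 17 lower and 10 higher members, a median of -0.10 and a camera adjusted p of 0.19. Its members CHI17 and P69A were higher by value, at 0.72 and 0.35. Over 5 samples limma called 0 of the 27, over all probe sets or adjusted over the list alone, and with 8 arrays 5 passed over all probe sets and 8 adjusted over the list alone. In the reassigned version, 18 of 23 members were lower (median -0.30, camera adjusted p = 0.00761), but adjusted p = 0.86 with an estimated correlation and 0.299 with that 3' minus 5' difference as a covariate. Of these 23, 5 passed adjusted over the list alone in the 5 sample fit, on a list drawn up after the gene ranking had been seen.

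The fixed list of cytosolic ribosomal proteins had all 6 probe sets, of 5 genes, lower, with a median of -0.19 and a camera adjusted p of 0.0158, but adjusted p = 0.887 with an estimated correlation. RPS25 differed by -0.28, RPL3 by -0.23 and rpl38 by -0.18, each without passing alone over 5 samples. With 8 arrays 3 of the 6 passed over all probe sets, both of RPS25 and that of RPL3. The auxin response list had 12 of 14 probe sets higher, a median of 0.21 and a camera adjusted p of 0.0387, but adjusted p = 0.887 with an estimated correlation. The 14 probe sets came from 7 genes with 2 each, so they are not independent of each other. No auxin probe set passed alone over 5 samples. With 8 arrays 1 passed over all probe sets, the IAA27 probe set that was lower in antisense (difference -0.22 over 8 arrays, limma adjusted p = 0.0396). The auxin adjusted p was 0.162 without wild type array 4 and 0.0540 without antisense array 2, and the median was 0.34 without antisense array 4. IAA3, IAA7 and IAA17, members of the Aux/IAA family of auxin-responsive repressors, had 2 probe sets each, which differed by 0.47 and 0.19, 0.49 and 0.15, and 0.45 and 0.45. The larger IAA3 and IAA7 values came from probe sets below the 6.71 reached by reporter probe sets, with wild type means of 6.07 and 4.60. Their brighter probe sets, at 9.06 and 8.68, gave the smaller values. Without wild type array 4 the larger IAA7 value became 0.29 and 1 of the IAA17 values 0.27. The 2 probe sets of IAA27 differed by -0.24 and 0.21, the latter at a wild type mean of 5.03, and those of IAA2 by -0.16 and 0.03. Over 8 arrays the adjusted p was 0.00455 for ribosomal proteins and 0.0238 for both the auxin and the carotenoid list, and none passed with an estimated correlation. The 3' minus 5' difference of control transcripts, a sign of RNA quality, was higher in antisense by 0.10 on average. With it as a covariate, chosen after the data were examined, the adjusted p was 0.0858 for ribosomal proteins and 0.375 for auxin. Both calls were also lost under quantile normalization, and the auxin call when each array's median was subtracted (adjusted p = 0.0798, range over all settings 0.00752 to 0.887). The reassigned members gave an adjusted p of 0.096 for ribosomal proteins and 0.0843 for auxin.

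Of the 909 named probe sets 103 passed with 8 arrays, 45 higher and 58 lower. The 12 largest differences per direction among those without overlap between genotypes also took in Wiv-1, an extracellular invertase, at -1.20 over 5 samples, LOC544312 at -1.44, LOC544267 at -1.29, ODC, an ornithine decarboxylase, at 0.66, AG1, a homologue of AGAMOUS, at 0.83, PDH at 1.21, CELLULASE at 0.79 and XET4 at 0.57. XET4 read 5.28 on antisense array 4 and 5.85 to 6.30 on antisense arrays 1 to 3, and its difference was 0.95 without antisense array 4. None of them passed over 5 samples. AG1 (5.53 in antisense, 4.69 in wild type) and XET4 (5.66 and 5.09) had mean signals below the 6.71 reached by reporter probe sets, so their differences are of uncertain size.

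In the cell wall list 20 of 42 probe sets were higher and 22 lower, with XTH6 at 0.88, TBG6 at 0.57 and TBG5 at 0.47 (both beta-galactosidases) and XTH3 at -1.03. None passed over all probe sets in the 5 sample fit, and the list's camera adjusted p was 0.721. With 8 arrays as separate samples, 8 higher and 4 lower members passed over all probe sets, XTH6, TBG6, TBG5 and XTH3 among them. Over 5 samples the phenylpropanoid list had 3 of 9 members passing when adjusted over the list alone. THT1-3 and THT7-8, which encode tyramine hydroxycinnamoyl transferases, were at -1.36 and -0.93, and the chitinase CHI17 at 0.72, while the list's camera adjusted p was 0.866. The glycolysis list (camera adjusted p = 0.721) had 1 such member, PPCK1, with hexokinase hxk1 at 0.30. The heat shock list (camera adjusted p = 0.272) had 1, HSP17-6 at 0.40. In fry's test for change in either direction, the phenylpropanoid, glycolysis and ribosomal lists passed, each with an adjusted p of 0.00673. With reassigned members these became 0.168, 0.0632 and 0.00186. Over 5 samples limma called 0 of the reassigned phenylpropanoid, glycolysis and heat shock members adjusted over the list alone. In the nitrogen list all 5 probe sets were lower (adjusted p = 0.19), among them the 2 probe sets of gts1 at -1.43 and -0.19 and the ammonium transporter AMT1-2 at -1.06. The means of AMT1-2, 5.57 in antisense and 6.63 in wild type, lay below the 6.71 reached by reporter probe sets. The -1.43 of gts1 became -0.90 without antisense array 4 and -0.93 without wild type array 1. The reassigned nitrogen list had 10 of 11 lower (camera adjusted p = 0.0377), but adjusted p = 0.86 with an estimated correlation. With the defence and carotenoid lists it made 3 reassigned lists that passed.

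Photosystem and light harvesting genes differed little. Their 7 probe sets had a median difference of -0.01 at log2 signals near the top of the range, such as 14.27 for CAB4 in antisense, where saturation was not tested (camera adjusted p = 0.866). In the carotenoid list 8 of 10 were higher, with a median of 0.10 and PSY2, a phytoene synthase, at 0.34 (camera adjusted p = 0.19). PSY2 read 9.91 on antisense array 4 and 10.40 to 10.45 on antisense arrays 1 to 3, and its difference was 0.60 without antisense array 4. The reassigned carotenoid list had 17 of 22 higher (camera adjusted p = 0.00761), but adjusted p = 0.86 with an estimated correlation. The abscisic acid list of 5 had a median of 0.77, that of LE16 (camera adjusted p = 0.214), which rested largely on antisense array 4. LE16 read 12.60 on that array, 11.61 to 11.65 on antisense arrays 1 to 3 and 11.11 to 11.71 on the wild type arrays. TAS14, a dehydrin, read 10.58 on antisense array 4 and 6.57 to 7.01 on the other arrays. Jasmonate, ethylene, starch, antioxidant and cell cycle lists gave camera adjusted p-values of 0.628 to 0.721. The fruit and flower marker list also gave 0.721, with a median of 0.01. The fixed trichome, phloem and xylem, and root markers had too few probe sets for a test, and the fixed GABA shunt had 4, with differences of -0.13 to 0.07. These depended on single arrays. GABA-TP1, at -0.13, became -0.40 without wild type array 1 and 0.09 without wild type array 4. With reassigned members the tricarboxylic acid cycle, the pathway of the antisense target, had 8 of 10 probe sets lower (median -0.04, camera adjusted p = 0.367). The reassigned root markers (7 probe sets), GABA shunt (5) and gibberellin list (10) each gave 0.683, the proteasome list 0.181, and the senescence and dioxygenase lists 0.886 each.

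**Figure D3:**
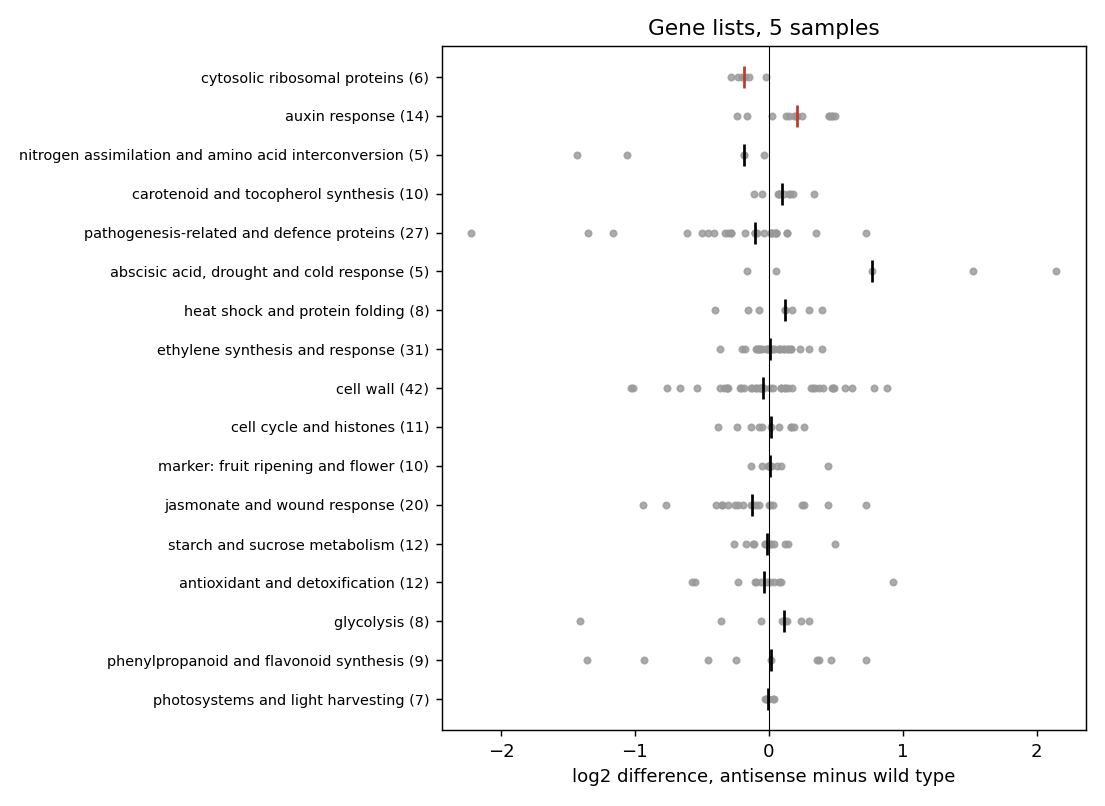
Log2 difference, antisense minus wild type, of each probe set (grey) of the 17 tested lists, with probe set numbers in parentheses and a bar at the median. Red bars mark the 2 lists that passed with a preset correlation, at -0.19 and 0.21.

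Control transcripts were probed at both ends, and their mean 3' minus 5' log2 difference was higher in the antisense samples on average. It was 0.64 to 0.73 on the antisense arrays, 0.69 on wild type array 1 and 0.52 to 0.54 on wild type arrays 2 to 4. Counted over samples the antisense excess was 0.10, with p = 0.3 in an exact two-sided permutation test that cannot go below 0.1. It was 0.15 without wild type array 1 and 0.07 to 0.13 without any other 1 array. With this difference as a covariate DES differed by -0.81, P4 by -0.69, Wiv-1 by -0.72, TBG6 by 0.37 and TBG5 by 0.31. PSY2 differed by 0.10 and gts1 by -2.38, and the same probe sets of IAA7 and IAA17 as above by 0.29 and 0.20. These genes were picked among the named probe sets whose difference changed markedly with the covariate. LOC543878, TSI-1, NP24-I, Dea1 and PPCK1 were not among those.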

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

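The splits of the 8 arrays and of the unadjusted p-values were tested only after the result was seen, and the 3' minus 5' difference as a covariate was chosen after the data were examined. Of 16 groups of 4 array-level values, 3 held a value standing apart. Chance gives about 1 in 20 among independent values, and more here, since near-identical arrays lie together in both genotypes and can make any other array of the group look apart. Wild type array 1 had a mean 3' minus 5' difference of 0.69, above the other wild type arrays. Wild type array 4 had an interquartile range of 3.32, above the rest of its group. Antisense array 4 had a mean correlation of 0.990 with the other arrays, below its group. Over 5 samples, 932 probe sets had an unadjusted p under 0.05 (476 without antisense array 4, 1409 without wild type array 1), 2 of the 10 splits gave as many, and the highest other, wild type arrays 2 to 3 with wild type array 4 against the rest, gave 1258; 10 splits are too few for a share under 0.05.

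The count of passing probe sets was 0 with 5 samples and 844 with 8 arrays, where leaving out 1 array gave 124 (antisense array 2) to 1817 (wild type array 1). Among the 10 splits of the 5 samples, antisense array 4 with wild type array 1 against the other samples called 5 probe sets. Each other split, the real one included, called 0. In data simulated with no genotype difference and the same repeat arrays, the 8 array fit called a median of 175.5 probe sets over 20 draws (highest 256), and the 5 sample fit called 0 in every draw with a median of 489 at an unadjusted p under 0.05. Counting near-identical arrays as separate samples may thus supply part of the 844. Of the 35 splits of the 8 arrays 1 gave as many, the real one, and the highest other gave 40, but only 3 splits keep near-identical arrays together, too few for a share under 0.05. A difference between the genotypes stays open for the rest, since simulated probe sets were independent and real ones need not be. The simulated spreads were also limma's moderated ones.

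For the ribosomal and auxin lists, 7 of the 10 splits called as many lists as the real 2, the highest other called 6, and 10 splits are too few for a share under 0.05. With the 3' minus 5' difference as a covariate the ribosomal median went from -0.19 to -0.15 (adjusted p = 0.0858) and the auxin median from 0.21 to 0.17 (adjusted p = 0.375). Both kept over 0.5 of their size while the calls ended, in a fit with 1 residual degree of freedom fewer. RNA quality and genotype cannot be told apart for these lists with 5 samples.

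The lower defence genes of the reassigned list went from a median of -0.30 to -0.18 with that covariate (adjusted p = 0.299). RNA quality may account for part of this difference. It cannot be told apart from genotype here, because wild type array 1 is the only wild type sample with a 3' minus 5' difference near those of the antisense arrays. That list was drawn up after the gene ranking had been seen, so its shift is not independent evidence.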

How the results depend on the processing

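The averaging of near-identical arrays, the random block, leaving out whole sets of such arrays, the covariate and the reassigned lists were tests chosen after the data had been examined. With limma on 5 samples 0 probe sets passed, and 0 under the planned settings for 5 samples, without any 1 array, without wild type 2 to 3 and with the covariate. The count was 844 with 8 arrays as separate samples, 597 with a replicate block on the 8 arrays, 32 with the RNA sample as a random block, and 1 without antisense 1 to 3. Whether the replicate numbers pair the arrays could not be told, since near-identical arrays of a genotype deviate alike. The correlation of deviations was -0.17 for number 1 and 0.15 to 0.31 for the others, and 3 of 8 arrays correlated best with their own number. With the block the fixed lists passing numbered 3. No value could be given for the targeted transcript. The 932 unadjusted p under 0.05 became 496 with the lowest 50% of probe sets left out (fewer tested), 2700 with 8 arrays and 2747 with the block, and ranged from 476 (without antisense 4) to 1409 (without wild type 1) when 1 array was left out; where a single antisense sample remained, it is assumed to vary like the others. The 844 became 52 with a log2 size of at least 1, 4211 with array weights and 126 with the unequal-variance test, and ranged from 124 to 1817 with 1 array left out. The number of passing lists, 2, became 0 with quantile normalization, an estimated correlation or directional fry, 3 with fry for change in either direction (ribosomal, glycolysis and phenylpropanoid; with reassigned members 1, ribosomal), and 1 with medians subtracted, the lowest 25% left out, the covariate, or antisense 1 to 3 left out (in these last 2 settings neither the ribosomal nor the auxin list), and ranged from 1 to 4 with 1 array left out. The auxin median lost its call at 0.22 (quantile), 0.24 (medians), 0.21 (lowest 25%, and, unchanged, the estimated correlation and both forms of fry), 0.15 (antisense 1 to 3 left out), 0.17 (covariate) and 0.20 (reassigned members); without 1 array it was 0.15 to 0.34, losing the call without antisense 2 or wild type 4. The ribosomal median lost its call at -0.15 (quantile, and covariate), -0.17 (antisense 1 to 3 left out), -0.10 (reassigned members) and, at an unchanged -0.19, with the estimated correlation and directional fry; without 1 array it stayed called at -0.21 to -0.18. The cause was not tested. Among 104 named probe sets, 9 had the other sign without antisense 4, 6 with the covariate, 5 without wild type 4, 3 without wild type 1 and at most 2 under each other setting. Adjusted p over these settings was 0.00752 to 0.887 for auxin and 0.00455 to 0.887 for ribosomal proteins.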

Other observations

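The genes of this part were chosen after their values were seen, and no group was formed from them. LAPA1, a leucine aminopeptidase, read 10.71 on antisense array 4 and 10.78 on wild type array 1, with 7.74 to 7.87 on antisense arrays 1 to 3 and 8.82 to 9.31 on wild type arrays 2 to 4. A probe set of ARG2, an arginase, read 11.61 and 11.42 on the same pair of arrays, 9.56 to 9.68 on antisense arrays 1 to 3 and 10.56 to 10.61 on wild type arrays 2 to 4. Their genotype differences were -0.40 and -0.25 over 5 samples, and neither passed (limma adjusted p = 0.913 and 0.912). Over 8 arrays the differences were -0.93 and -0.67, also without passing.

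Of the 63 reporter and construct probe sets, 1 passed when adjusted over these 63, and it was lower in antisense (difference -0.35, limma adjusted p = 0.0375). The largest excess in antisense was 0.27. Both antisense samples lay above all wild type samples in 10 of the 63, where chance gives 10% of them.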
